A study of Mus musculus with 23 samples.

How the data were processed

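Total RNA of mouse striatal tissue was extracted with Trizol LS, and biotinylated cRNA prepared from 6 ug was hybridised to Affymetrix arrays, per the labels' protocols. The 23 arrays comprise 11 WT and 12 dKO mice at 3 ages. Genotype and age were taken from the sample labels, and replicate numbers from the sample titles. The design text states at least 3 biological replicates per group and littermate controls, and does not pair single animals. The smallest median absolute difference between any 2 arrays was 0.104, so no array repeats another.

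The deposited values are log2 values made with RMA, per the submitters' processing notes, which give no version. The software, the annotation release and the array design are not given in the sources used here. The values themselves show that each probe set was centred near its median: 39666 of 45101 probe sets (87.95%) have an array at exactly 0, at rank 10 to 14 of the 23. Which arrays set the centre is not stated. Levels are therefore lost, genes cannot be ranked by brightness, and differences between arrays remain. Values run from -7.11 to 8.13 and array medians from -0.00934 to 0.0152. The values were read from the series value table. In the authors' normalized values, 2 columns carry the same name and were not used, and the other 21 columns were identical (largest difference 0). Gene symbols came from the latter: 38143 probe sets have 1 symbol, 1253 several and 5705 none, and only the first kind was tested. Symbols of 1160 genes were updated through a RefSeq gene table of assembly GRCm38.p6, which held 18344 (88.64%) of the 20694 genes and was used only for names, chromosomes and gene order.

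No further normalization was done. The rule set before the data were examined took the probe set with the highest mean per gene. Centred values have no level, so the probe set with the largest SD over the 23 arrays, chosen without the group labels, stood for each of the 9654 genes with several. That SD includes the differences between groups, so the rule favours probe sets with larger changes. Fold changes of such genes can therefore be larger than with other choices of probe set, which are given as alternatives. The filter on dim probe sets could not run for the same reason. One mean per group (6 groups) was fitted to all 23 arrays with lmFit of limma 3.58.1 in R 4.3.3, with no covariates and default eBayes (residual df 17, prior df 4.58, total 21.6). Comparisons were dKO against WT at each age, the differences between these effects, WT at 6 months against 6 weeks, and the mean effect. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided.

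Named genes are, at each age, all probe sets of Ezh1 and Ezh2 and the 10 largest rises and 10 largest falls among called genes whose dKO arrays all lie beyond all WT arrays, leaving out predicted or clone-named genes. To these were added the 5 largest changes each way between ages and in WT with age, and up to 4 called members per list with the largest change at 6 months. List members named for other comparisons, the genes called at all 3 ages, and further members of a list were chosen after their values were seen. Some genes that these rules name are not reported. For lists without a called member, the members with the largest change replaced those with the highest level. Gene lists (15) and cell type marker lists (12) were fixed from textbook knowledge before the data were examined, and gave 81 tests over 3 ages. Each was tested with limma's camera at the preset correlation of 0.01, with camera at an estimated correlation, and with fry. Benjamini-Hochberg adjustment ran over lists and ages. The preset test called 45 of 81, the estimated one 12, both 12, and fry 31. Overlaps between ages used Fisher's exact test, two-sided, and array quality used two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

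The fit was tested on simulated data with each gene's pooled spread, with 67, 67 and 66 of 20694 genes changed by each effect size. At a true log2 fold change of 0.5, 1 and 2 it recovered 35.8%, 89.6% and 98.5% at 6 weeks, 41.8%, 95.5% and 100% at 3 months, 61.2%, 94% and 100% at 6 months, and 14.9%, 76.1% and 98.5% for the change from 6 weeks to 6 months. It called 5, 13, 10 and 9 unchanged genes, and none in the wrong direction. Simulated genes were independent and all simulated arrays equally noisy, whereas weights fitted to the real arrays ran from 0.332 to 4.79. These rates may therefore not hold for the real arrays. Alternatives tried were quantile normalization, median centring, other choices of probe set, fits on 2 groups, trended and robust eBayes, array weights, stricter thresholds, Xist and the Gapdh 3' minus 5' difference as covariates, a block on replicate number, and leaving out each array in turn. Added after seeing the data were the probe set of highest mean, a filter on SD and only high-Xist arrays at 6 months. Cortical and choroid plexus marker medians as covariates, without and with the thalamic or pallidal one, and leaving out genes near Ezh1 were also added then. The highest mean is that of centred values, so it does not rank probe sets by brightness.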

Results

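Gene expression was measured on 23 arrays of mouse striatal tissue. The striatum is the input nucleus of the basal ganglia, and most of its neurons are medium spiny neurons. The mice were wild type (WT) or double knockouts (dKO) of Ezh1 and Ezh2, the alternative catalytic subunits of Polycomb repressive complex PRC2, which places a repressive methyl mark on histones. There were 3 WT and 3 dKO arrays at 6 weeks, 4 WT and 3 dKO at 3 months, and 4 WT and 6 dKO at 6 months. Controls were littermates matched for age and sex, per the design text. Values were RMA log2 values centred per probe set, so they gave differences between arrays and no level of a gene. The number of arrays limits the precision. Changes are given as log2 fold changes of dKO over WT with the standard error after ±, and adjusted p-values are from limma after Benjamini-Hochberg adjustment over 20694 genes.

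Ezh1 was lower in dKO at every age, and Ezh2 did not pass the test at any. The Ezh1 probe set with the largest spread had a mean of 2.21 ± 0.121 in WT and 0.161 ± 1.14 in dKO at 6 weeks (SD, n = 3 and 3). It had 1.56 ± 0.164 and -0.436 ± 0.336 at 3 months (SD, n = 4 and 3), and 1.65 ± 0.0742 and -0.446 ± 0.374 at 6 months (SD, n = 4 and 6). The log2 fold changes were -2.05 ± 0.34, -2.0 ± 0.32 and -2.10 ± 0.27, with adjusted p of 0.0153, 0.00246 and 1.37e-05. The 3 further Ezh1 probe sets were lower at each age as well, with log2 fold changes between -0.83 and -1.86, and 1 of them missed the threshold at 3 months (adjusted p = 0.0518, over all probe sets). The single Ezh2 probe set gave -0.40 ± 0.20, -0.45 ± 0.19 and -0.43 ± 0.16, with adjusted p of 0.590, 0.557 and 0.0643. Which part of either gene was deleted is not stated in the sources used here, so a probe set may lie outside it and then checks nothing. At 6 weeks the dKO arrays read -0.37, -0.62 and 1.47 for Ezh1, against 2.07 to 2.28 in WT. The array at 1.47 goes against its label and is called the library labelled dKO replicate 3. Without it, 52 genes were higher and 14 lower at 6 weeks.

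**Figure D1:**
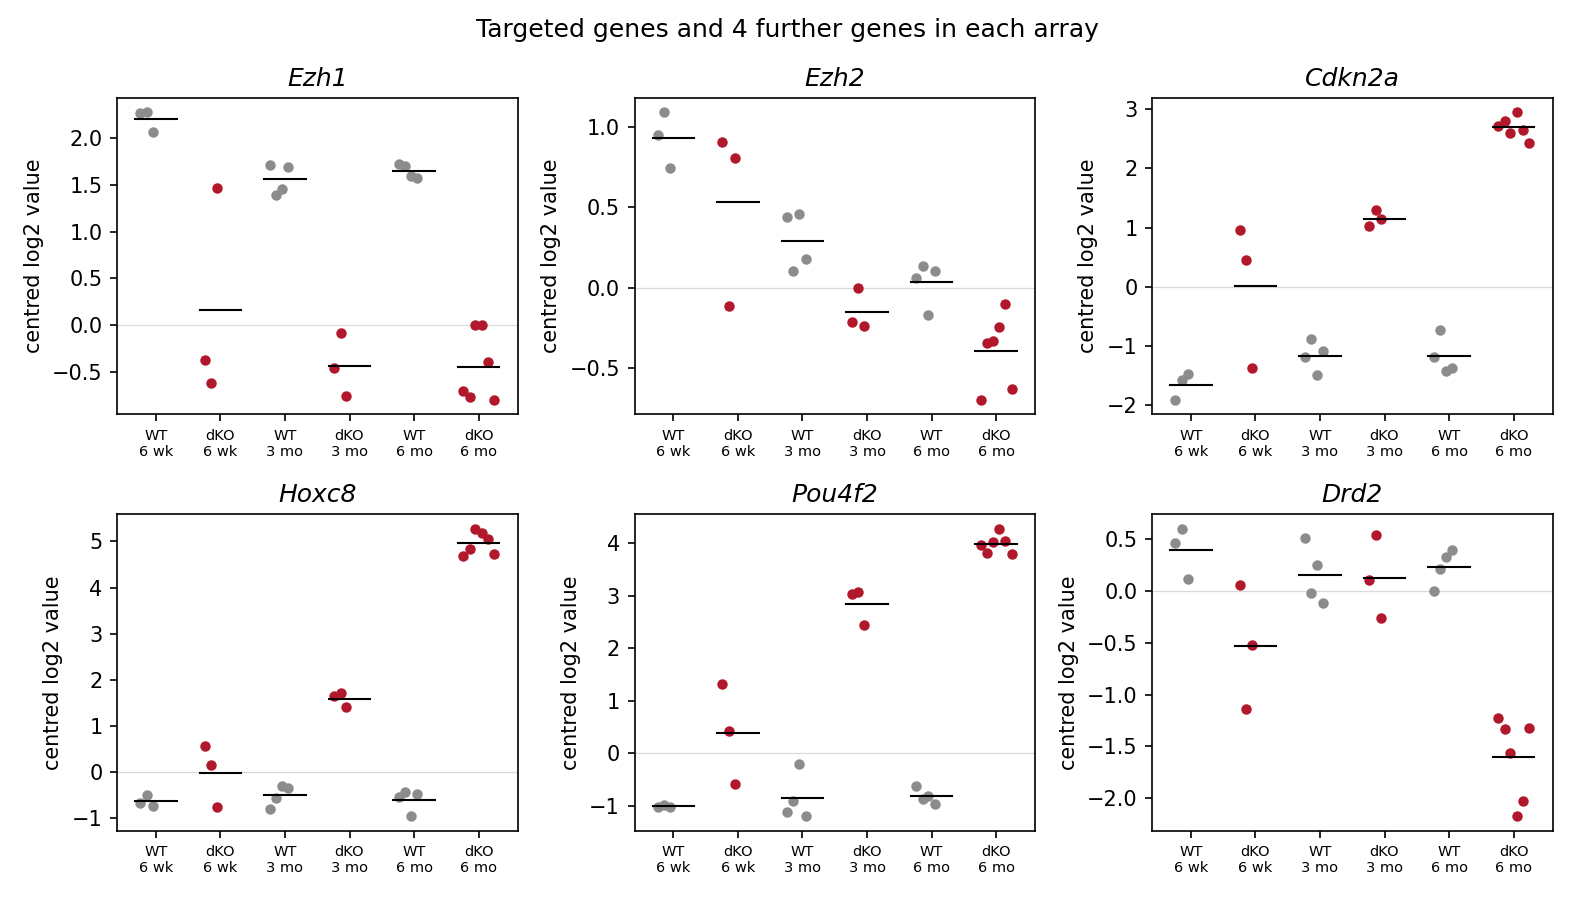
Centred log2 value of Ezh1, Ezh2, Cdkn2a, Hoxc8, Pou4f2 and Drd2 in each of the 23 arrays, by genotype and age (WT grey, dKO red; wk, weeks; mo, months); each point is an array and each bar the mean of its group. Hoxc8 rose by 5.57 and Drd2 fell by 1.84 in dKO at 6 months, and the library labelled dKO replicate 3 at 6 weeks has the high dKO value of Ezh1, 1.47.

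At 6 weeks, 25 genes were higher and 18 lower in dKO (n = 3 and 3). Cdkn2a, whose products inhibit the cell cycle, rose by 1.66 ± 0.35 (adjusted p = 0.0481), a 3.17-fold difference. Gfap, the intermediate filament of astrocytes, rose by 1.21 ± 0.23 (adjusted p = 0.0331), and Spp1, the secreted glycoprotein osteopontin, rose by 1.73 ± 0.33 (adjusted p = 0.0331). Slc17a6, a vesicular glutamate transporter of subcortical neurons, rose by 2.11 ± 0.42 (adjusted p = 0.0384). Cuedc1 had the largest rise, 2.70 ± 0.21 (adjusted p = 3.82e-07), and Patj, Wdfy1, Tusc1, Lsm12 and Greb1l rose by 0.99 to 1.70. Among the genes that fell were Taf15, an RNA-binding protein, by 1.77 (adjusted p = 0.0384), Gdpd1 by 1.47 and the zinc finger gene Zfp932 by 1.42 (adjusted p = 3.92e-06). Dusp14, Clvs1, Il17rc, Slc24a2, Cd72 and Mysm1, a histone H2A deubiquitinase, fell by 0.82 to 1.13. In each of these genes all 3 dKO arrays lay beyond all 3 WT arrays. Of 40 located 6-week calls other than Ezh1, 9 were on its chromosome, 11, where 3.175 would be by chance. Which of the genes named here are among these 9 is not given. A genetic background differing between the mice may therefore contribute to these differences, as taken up below.

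The marker and pathway lists at 6 weeks held few genes that passed over all genes tested. Medium spiny neuron genes were lower as a set (median -0.52, 40 measured, none with a positive log2 fold change). None was called with limma over all genes, where 1876 genes had an unadjusted p under 0.05, and 28 were lower when adjusted over the list alone. The set test gave an adjusted p of 1.03e-24 with the preset correlation and an adjusted p of 0.106 with an estimated correlation. The list's median per array was 0.24 to 0.51 in WT and 0.33, -0.48 and -0.20 in dKO. Reactive astrocyte genes were higher as a set (median 0.31). Of 13, 2 rose, Gfap and Cd44, a cell surface receptor for hyaluronan (0.92 ± 0.19), and 5 rose adjusted over the list alone (set adjusted p = 2.27e-06, and adjusted p = 0.033 with an estimated correlation). The p53 and cell death list of 31 genes was also higher as a set (median 0.20, 7 adjusted over the list alone, set adjusted p = 2.27e-06, and adjusted p = 0.0181 with an estimated correlation). Of 10 thalamic or pallidal neuron markers, Slc17a6 rose, and 7 rose adjusted over the list alone (median 0.98, set adjusted p = 5.85e-08, and adjusted p = 0.0809 with an estimated correlation). Cortical marker medians, which moved beside these groups, read -0.90, 0.99 and 0.53 in the 3 dKO arrays and -0.67 to 0.09 in WT.

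Leaving out single arrays moved the 6-week counts more than 1.5 times: without WT replicate 1, 2 or 3 of that age, 2, 3 or 15 genes were higher and 1, 1 or 10 lower, and without dKO replicate 1 or 2, 121 or 4 were higher and 152 or 2 lower, while WT replicate 3 of 6 months left 15 and 11, and WT replicate 2 of 6 months left 11 lower. Quantile normalization turned the split from 58.1% higher to 38.6% (17 higher, 27 lower), the fit on the 6-week arrays alone gave 4 and 3 and array weights 1231 and 1360, and with the probe set of highest mean Patj, Clvs1 and Gdpd1 changed sign (-0.06, 0.06 and 0.06) while Cuedc1, Taf15 and Wdfy1 read 0.28, -0.02 and 0.00. Cdkn2a lost its 6-week call in most alternatives, with 0.745 under array weights, and Zfp932 kept its 6-week call throughout. Every other gene named above as changed at 6 weeks lost the call in at least 1 alternative, Cd44 not being followed there. Slc17a6 read 0.87 with the 3 tissue covariates (adjusted p = 0.897), the calls of Gfap and Spp1 ended in 9 and 7 alternatives (adjusted p up to 0.213 and 0.29), and with the mean of probe sets Il17rc, Mysm1 and Greb1l read -0.39, -0.30 and 0.51. Slc17a6 is itself on the thalamic or pallidal list, whose median is 1 of those covariates. Its lost call there therefore does not decide on neighbouring tissue. Of all genes, 17.8% had no overlap between the genotypes, against 10% by chance.

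By 3 months 80 genes were higher in dKO and 6 lower (n = 4 and 3), and 47 of the 80 were raised at least 2-fold. Developmental transcription factors led the list. Pou4f2, a POU factor of retinal ganglion cells, rose by 3.71 ± 0.29 (adjusted p = 1.82e-07), a 13.1-fold difference, and Twist1, a factor of mesoderm and neural crest, rose by 3.39 ± 0.33 (adjusted p = 5.32e-06). Irx5 rose by 2.63 ± 0.21 and Hoxc8 by 2.09 ± 0.22 (adjusted p = 1.39e-05). Aldh1a2, an enzyme of retinoic acid synthesis, rose by 2.67 ± 0.39 (adjusted p = 0.000724). Calcr, the calcitonin receptor, Cdkn2a and Skor1 rose by 2.29 to 2.47, and Wt1 by 2.0 ± 0.23. Among the 6 genes that fell were Ezh1, the noncoding transcript Ipw (-0.74), Clip1 (-0.70), Smim3 (-0.57) and Pgr, the progesterone receptor (-0.52).

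Of 35 measured Hox genes, which pattern the body axis, 5 rose at 3 months and none fell, and 7 rose adjusted over the list alone (median 0.24, set adjusted p = 1.13e-11, and adjusted p = 0.033 with an estimated correlation). Hoxd8 and Hoxc4 rose by 1.63 and 1.61. Of 89 non-Hox developmental transcription factors, 18 rose and 32 did so adjusted over the list alone, with none lower (median 0.26, set adjusted p = 2.38e-30, and adjusted p = 0.00256 with an estimated correlation). No MHC class I or complement gene was called over all genes, where limma left 1450 genes at an unadjusted p under 0.05, and 6 of 12 rose adjusted over the list alone (median 0.35, set adjusted p = 1.41e-09, and adjusted p = 0.0279 with an estimated correlation). Reactive astrocyte genes had 2 of 13 higher, S100a10 (1.15 ± 0.20) and Cd44 (1.10 ± 0.18). Adjusted over the list alone 5 rose and 1 fell (set adjusted p = 2.3e-06, and adjusted p = 0.033 with an estimated correlation). Activated microglia genes had 2 of 17 higher, Spp1 (1.65 ± 0.31) and H2-Ab1 (0.74 ± 0.16), a class II antigen presentation gene, and 7 adjusted over the list alone (set adjusted p = 3.83e-08, and adjusted p = 0.0423 with an estimated correlation). Synaptic and excitability genes were lower as a set (median -0.09) with none of 34 called and 1 lower adjusted over the list alone (set adjusted p = 4.37e-04, and adjusted p = 0.0198 with an estimated correlation). The 40 medium spiny neuron genes had a median of -0.01, with none called either way (set adjusted p = 0.415). The actin control probe sets had a 3' minus 5' difference 0.157 larger in dKO than in WT at 3 months (exact permutation p = 0.0286, adjusted p = 0.257).

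Without WT replicate 2, dKO replicate 1 or dKO replicate 2 of 3 months, 52, 42 or 39 genes were higher, and the number lower was 2 without WT replicate 2 or dKO replicate 1, 3 without WT replicate 4, 11 without dKO replicate 3 and 13 without WT replicate 1 of 6 months. Quantile normalization gave 178 higher and 23 lower, and Eya1, a direct pathway list member that rose by 1.0, read -0.01 with the probe set of highest mean. With the mean of probe sets Ipw and Clip1 read -0.32 and -0.28, with adjusted p of 0.784 and 0.27, and Skor1 1.19, still called. The calls of Smim3, Pgr, Calcr, S100a10 and Spp1 also ended in some alternatives (adjusted p up to 0.197, 0.342, 0.156, 0.074 and 0.31).

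At 6 months 1874 genes were higher and 1853 lower in dKO (n = 4 and 6), or 18.01% of those tested, and 202 and 121 of them differed at least 2-fold. The largest rises were in Hox and other patterning genes: Hoxc8 by 5.57 ± 0.18 (adjusted p = 2.11e-15), a 47.4-fold difference, Hoxd10 by 5.14 ± 0.16, Pou4f2 by 4.81 ± 0.24 and Hoxa9 by 4.70 ± 0.13. Hoxc10, Twist1, Skor1, Hoxd8 and Slc6a5, the glycine transporter of inhibitory neurons of the hindbrain and spinal cord, rose by 4.04 to 4.75. Cdkn2a rose by 3.87 ± 0.28 (adjusted p = 1.39e-09), a 14.6-fold difference. Gpx6, a glutathione peroxidase, fell by 2.51 ± 0.25 (adjusted p = 3.93e-07), Ido1, a tryptophan-degrading enzyme, fell by 2.20 ± 0.22, and Pde7b, a cAMP phosphodiesterase, by 1.90 ± 0.20. Drd2, the dopamine receptor of indirect pathway neurons, fell by 1.84 ± 0.22 to 0.28 of the WT value, and Adora2a, the adenosine receptor of the same neurons, fell by 1.65 ± 0.20. All 6 dKO arrays lay beyond all 4 WT arrays for each of these genes. Pmch had the largest fall, 3.32 ± 0.62, with overlap between the genotypes. Krt12, with none, fell by 2.70 ± 0.84, and Phex, Nexn, Coch, Gask1b and Slc35d3 fell by 1.87 to 2.11.

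**Figure D2:**
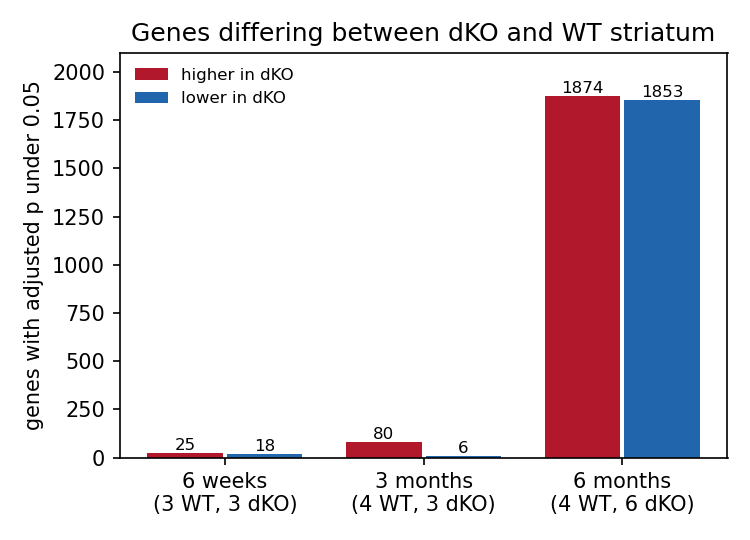
Number of genes with limma adjusted p under 0.05 that were higher (red) or lower (blue) in dKO than in WT striatum at each age; the number of arrays is under each pair of bars, and the bars start at 0. The counts were 25 and 18 at 6 weeks, 80 and 6 at 3 months, and 1874 and 1853 at 6 months.

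Of the 35 Hox genes 31 rose at 6 months and none fell (31 and 1 adjusted over the list alone), with a median of 1.32. The set adjusted p was 1.35e-43, and adjusted p = 2.06e-04 with an estimated correlation. The list's median per array was 0.93 to 1.40 in the 6 dKO arrays and -0.20 to 0.00 in the 4 WT arrays. Of 89 non-Hox developmental transcription factors, 58 rose and none fell (64 and 0 adjusted over the list alone), with a median of 0.77, a set adjusted p of 7.42e-50, and adjusted p = 2.06e-04 with an estimated correlation. Pou4f1, Tal1, Tbx20 and Wt1 rose by 3.86, 3.69, 3.61 and 3.6. Cyclin-dependent kinase inhibitors had 4 of 7 higher, Cdkn2a, Cdkn1a (1.62 ± 0.26), Cdkn2b (1.41 ± 0.14) and Cdkn2c (0.57 ± 0.10). Adjusted over the list alone 5 rose and 1 fell, with a set adjusted p of 3.23e-05, and adjusted p = 0.0198 with an estimated correlation. The p53 and cell death list had 4 of 31 higher and 1 lower (5 and 1 adjusted over the list alone). Its risers were Wt1, the proapoptotic genes Pmaip1 (2.35 ± 0.24) and Bid (1.02 ± 0.16), and Perp, and the set adjusted p was 0.0123, and adjusted p = 0.149 with an estimated correlation. Subunits of PRC1, the second Polycomb complex, had 6 of 18 higher (8 adjusted over the list alone), among them Cbx8 (0.55 ± 0.11), with a set adjusted p of 0.0137, and adjusted p = 0.252 with an estimated correlation. In the PRC2 list of 12, Ezh1, Aebp2 (-0.67 ± 0.17) and Jarid2 (-0.31 ± 0.09) fell and Phf1 (0.26 ± 0.08) rose, with 1 higher and 4 lower adjusted over the list alone (set adjusted p = 0.0902, but adjusted p = 0.0229 with fry, downward). This list holds the targeted genes Ezh1 and Ezh2, so its downward result was partly fixed by the knockout. It was not tested without them and says nothing on the other subunits as a set. Aebp2 read 0.04 with the probe set of highest mean.

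Medium spiny neuron genes fell at 6 months: 30 of 40 were lower and none higher (31 and 0 adjusted over the list alone), with a median of -0.75. The set adjusted p was 5.94e-22 with the preset correlation, with adjusted p = 0.128 with an estimated correlation and adjusted p = 3.18e-04 with fry, which tests the list's own direction. The list's median was -0.69 to -0.42 in the 6 dKO arrays and 0.03 to 0.20 in the 4 WT arrays, and the cortical marker medians ran from -0.90 to 0.31 in dKO and from -1.14 to -0.10 in WT. Besides Drd2, Adora2a, Ido1 and Pde7b, the fallers included Actn2 (-1.73 ± 0.19). Direct pathway genes had 4 of 10 lower and 1 higher (1 higher and 5 lower adjusted over the list alone; set adjusted p = 0.00614, and adjusted p = 0.366 with an estimated correlation). Drd1, the dopamine receptor of direct pathway neurons, fell by 1.15 ± 0.18, Chrm4 by 1.07 ± 0.14 and Tac1 by 0.43 ± 0.12, while Eya1 rose by 0.95 ± 0.18 (0.21 and not called with the probe set of highest mean). Indirect pathway genes had 5 of 7 lower over all genes and adjusted over the list alone (set adjusted p = 1.87e-04, and adjusted p = 0.106 with an estimated correlation), with Penk, the enkephalin precursor, down by 0.34 ± 0.10. Synaptic and excitability genes had 11 of 34 lower and 3 higher, the same counts adjusted over the list alone (set adjusted p = 0.0014, and adjusted p = 0.0279 with an estimated correlation). The potassium channel genes Kcnd2 (-1.27 ± 0.21) and Kcna4 (-0.86 ± 0.15) and the scaffold gene Shank3 (-0.83 ± 0.11) fell, and Dlg4 (0.72 ± 0.16) rose. Of 19 neuronal activity-induced genes, 4 fell, among them Homer1 (-0.76 ± 0.17) and Egr1 (-0.64 ± 0.17), and Btg2 rose, with the same counts adjusted over the list alone (set adjusted p = 0.147). Striatal interneuron markers had 3 of 13 lower, also adjusted over the list alone. Among them were Slc18a3 (-1.40 ± 0.18) and Slc5a7, which cholinergic neurons use (set adjusted p = 0.0833, but adjusted p = 0.0259 with fry).

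**Figure D3:**
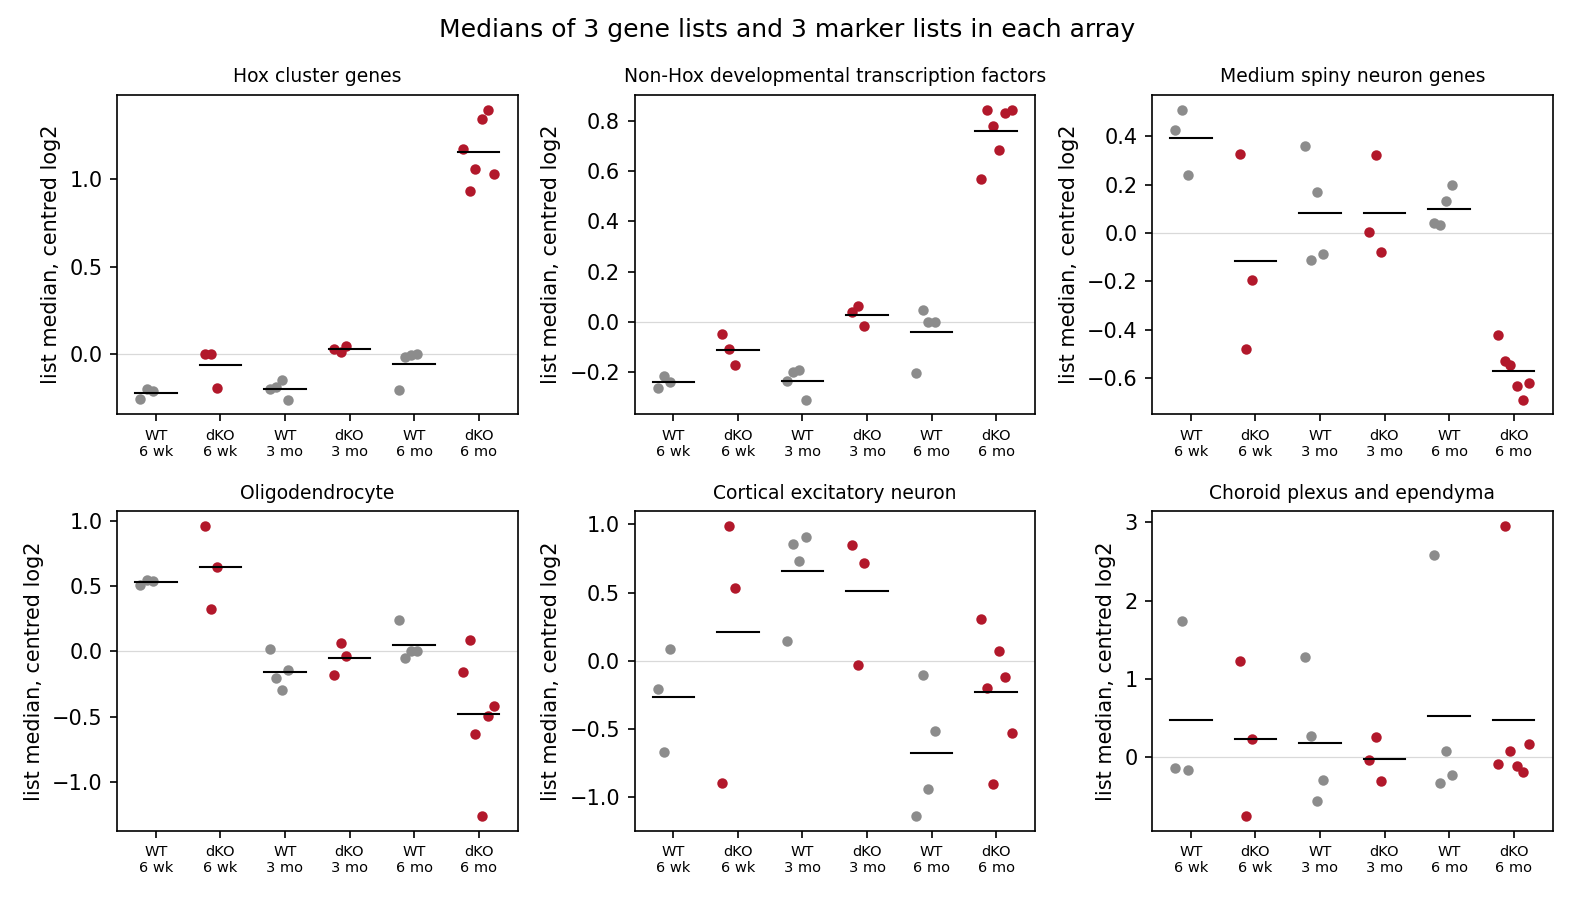
Median centred log2 value, in each of the 23 arrays, of the Hox, non-Hox developmental transcription factor and medium spiny neuron lists and of the oligodendrocyte, cortical neuron and choroid plexus marker lists, by genotype and age (WT grey, dKO red; wk, weeks; mo, months); bars are group means. At 6 months the Hox medians of the dKO arrays (0.93 to 1.40) lie above those of WT (-0.20 to 0.00), and choroid plexus markers are high in WT replicate 1 (2.59) and dKO replicate 2 (2.96).

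Glial and other cell markers moved in different directions at 6 months. Reactive astrocyte genes had 6 of 13 higher (7 adjusted over the list alone), including Serpina3n (2.03 ± 0.22), S100a10 (1.53 ± 0.17) and Vim (1.0 ± 0.16), with a set adjusted p of 0.00138, and adjusted p = 0.142 with an estimated correlation. Of 14 astrocyte markers 2 rose, Aldoc (1.29 ± 0.11) and Fgfr3, and 2 fell, Slc4a4 and Ntsr2 (4 and 5 adjusted over the list alone; set adjusted p = 0.973). Oligodendrocyte genes, most of which serve myelin, had 6 of 14 lower and none higher (10 lower adjusted over the list alone), including Ugt8a (-1.22 ± 0.33) and Gjb1 (-1.01 ± 0.19). Their median was -0.53, with a set adjusted p of 3.9e-05, and adjusted p = 0.366 with an estimated correlation. Oligodendrocyte precursor markers had 4 of 8 lower, also adjusted over the list alone, among them Cacng4 (-0.76 ± 0.14) and Bcas1 (-0.66 ± 0.13; set adjusted p = 0.0521, but adjusted p = 0.0317 with fry). Microglia markers had 3 of 18 lower, Fcrls (-1.48 ± 0.40), Aif1 and P2ry12, and 5 adjusted over the list alone (set adjusted p = 0.00735, but adjusted p = 0.481 with an estimated correlation and 0.111 with fry). Activated microglia genes had 3 of 17 higher, Ch25h, Cst7 and Ccl4, and 1 lower, Lpl (8 and 1 adjusted over the list alone; set adjusted p = 0.0264, but adjusted p = 0.395 with an estimated correlation and 0.0583 with fry). Interferon-induced genes had 6 of 21 lower, also adjusted over the list alone, including Gbp2 (-0.92 ± 0.21) and Gbp3 (-0.89 ± 0.14; set adjusted p = 0.00115, and adjusted p = 0.385 with an estimated correlation). Endothelial and mural markers had 3 of 14 lower, Emcn, Abcc9 and Kcnj8, and 7 adjusted over the list alone (set adjusted p = 0.00495, and adjusted p = 0.366 with an estimated correlation).

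The remaining lists had camera tests that missed the threshold at 6 months. MHC class I and complement genes had 2 of 12 higher, the peptide transporter genes Tap1 (0.48 ± 0.10) and Tap2 (0.31 ± 0.08), with the same count adjusted over the list alone (set adjusted p = 0.0927). BMP, Wnt and hedgehog genes had 8 of 41 higher, led by Sfrp2 (1.16 ± 0.22) and Wnt5a (0.98 ± 0.17), and 5 lower, led by Wnt2 (-0.85 ± 0.14; 9 and 5 adjusted over the list alone; set adjusted p = 0.21, but adjusted p = 0.0439 with fry, upward). Cholesterol synthesis genes had 1 of 20 higher, Lss (0.62 ± 0.15), and 3 lower, Sc5d, Msmo1 and Srebf2 (2 and 5 adjusted over the list alone; set adjusted p = 0.44). Cortical excitatory neuron markers had 3 of 14 higher, Neurod2 (1.68 ± 0.31), Nptx1 and Emx2, and 1 lower, Lamp5 (3 and 2 adjusted over the list alone; median 0.52, set adjusted p = 0.0902). Thalamic or pallidal markers had 2 of 10 higher, Lhx9 and Calb2, and 1 lower, Synpo2 (-1.84 ± 0.36), as when adjusted over the list alone (set adjusted p = 0.836). Blood markers had S100a8 and S100a9 higher (1.03 each) and Alas2 (-0.82) and Ptprc (-0.50) lower of 8, as when adjusted over the list alone (set adjusted p = 0.685), and their mean (0.05) and median (-0.17) differed in sign. None of 14 choroid plexus and ependyma markers was called by limma, over all genes or adjusted over the list alone, with 6270 genes at an unadjusted p under 0.05 (set adjusted p = 0.792), although WT replicate 1 and dKO replicate 2 had list medians of 2.59 and 2.96 and the other 8 arrays lay between -0.33 and 0.17. With the probe set of highest mean Neurod2, Lss, Tap1 and Ptprc read -0.12, -0.20, -0.06 and 0.00, so their probe sets disagree, and the calls of Phex (-0.0129), Synpo2 (-0.0471), Kcnd2 (-0.216), Ugt8a (-0.299), Sc5d (-0.113) and Cdkn2c (0.174) ended there too.

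No single array moved the 6-month counts more than 1.5 times, and 11% of all genes had no overlap between the genotypes against 0.952% by chance. Fitting the 6-month arrays alone gave 953 higher and 906 lower, and the Krt12 call ended under quantile normalization, array weights, the block on replicate number and high-Xist arrays alone, and without WT replicate 1, 3 or 4 or dKO replicate 3 or 6, with values over all settings of -3.547 to -2.374 and adjusted p up to 0.118. With the mean of probe sets Hoxa9, Skor1, Slc6a5 and Tbx20 rose by 2.58, 2.05, 2.09 and 1.405, all still called. Calls that ended in at least 5 alternatives were also those of Abcc9, Btg2, Ccl4, Cst7, Fgfr3, Lamp5, Nptx1, Perp, Phf1 and Slc5a7. Those of Fcrls, Aif1, P2ry12, Egr1, Homer1, Msmo1 and Ch25h ended only when the 6-month arrays were fitted alone. Other calls ended in at least 1 alternative too, among them Calb2 and Bcas1 (adjusted p up to 0.152 and 0.0642).

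Whether the dKO effect itself differed between ages was tested as a difference of differences. From 6 weeks to 6 months the effect grew or shrank in 212 genes, 143 upward and 69 downward. Hoxd10 had the largest upward change, 5.05 (adjusted p = 3.64e-11), followed by Hoxc8 (4.94), Hoxa9 (4.44) and Hoxc10 (4.26), and Gpx6 (-2.20), Ramp3 (-2.14), Cckar (-2.10), Igsf1 (-1.79) and Gkn3 (-1.79) had the largest downward changes. The call of Igsf1 ended in 9 alternatives (-0.34 with the probe set of highest mean, adjusted p up to 0.481), and those of Cckar (adjusted p up to 0.119) and Gpx6 (up to 0.0697) in 3 and 2. The effect on Cdkn2a rose by 2.20 (adjusted p = 0.0126). Of the 35 Hox genes 21 had an upward change (28 up and 1 down adjusted over the list alone; adjusted p = 9.53e-05 with an estimated correlation), as did 35 of the 89 other transcription factors (50 adjusted over the list alone). From 3 to 6 months 151 genes changed upward and 184 downward. Hoxd10 (4.76), Hoxa9 (4.63), Hoxc10 (3.76), Tbx20 (3.55) and Hoxc8 (3.48) led one side, and Gpx6 (-2.69), Gkn3 (-2.21), Dmkn (-2.11), Ido1 (-1.94) and Abi3bp (-1.83) the other, with the calls of Ido1 and Dmkn ending in 3 and 2 alternatives (adjusted p up to 0.129 and 0.108). With the mean of probe sets the changes of Hoxa9 were 2.46 from 6 weeks and 2.605 from 3 months and that of Tbx20 was 1.40, all still called. Medium spiny neuron genes had 13 of 40 with a downward change over this interval, including Drd2 (-1.81 ± 0.33) and Adora2a (-1.63 ± 0.32), and 27 adjusted over the list alone (set adjusted p = 1.47e-21, and adjusted p = 0.166 with an estimated correlation). From 6 weeks to 6 months limma called none of the 40, with 2911 genes at an unadjusted p under 0.05 (3 downward adjusted over the list alone, median -0.27, set adjusted p = 7.09e-04, and adjusted p = 0.646 with an estimated correlation). From 6 weeks to 3 months all 40 had a positive value and none was called, with 1139 genes at an unadjusted p under 0.05 (none adjusted over the list alone, median 0.51, set adjusted p = 9.57e-15, and adjusted p = 0.353 with an estimated correlation). Between 6 weeks and 3 months 3 genes passed: Irx5 (1.99) and Zfp932 (1.24) upward and Cuedc1 (-2.44) downward. None kept its call throughout: Cuedc1 read -0.08 with the probe set of highest mean (adjusted p = 0.988) and -0.85 with the mean of probe sets, and the adjusted p of Irx5 and Zfp932 reached 0.319 and 0.196.

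These interaction counts moved with single arrays. From 6 weeks to 6 months 122, 123 and 129 genes were called without WT replicate 1, WT replicate 2 and the library labelled dKO replicate 3 of 6 weeks. Without dKO replicates 2 and 6 of 6 months, 470 and 351 were called. From 3 to 6 months the count was 166, 180 and 173 without WT replicates 2, 3 and 4 of 3 months. It was 198 and 118 without dKO replicates 1 and 2 of 3 months. It was 187 and 180 without WT replicates 3 and 4 of 6 months, and 680 and 548 without dKO replicates 2 and 6 of 6 months. For the 3 genes between 6 weeks and 3 months the count was 12 without dKO replicate 1 of 6 weeks, 6 without WT replicate 3 of 3 months, 8 without dKO replicate 3 of 3 months and 6 without dKO replicate 4 of 6 months, and the share upward went from 66.7% to 90.9% with quantile normalization and to 80% with median centring.

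The same genes recurred across ages more often than independent lists would share. Of the 25 genes higher at 6 weeks, 6 were higher at 3 months (0.0966 by independence, Fisher's exact test, adjusted p = 9.22e-10) and 16 at 6 months (2.26 by independence, adjusted p = 5.34e-11). Of the 80 genes higher at 3 months, 66 were higher at 6 months (7.24 by independence, adjusted p = 1.28e-54). Among genes lower, 12 were shared by 6 weeks and 6 months (1.61 by independence, adjusted p = 4.29e-09), 3 by 3 and 6 months (0.537 by independence, adjusted p = 0.0117) and 1, Ezh1, by 6 weeks and 3 months. The ages share no control arrays, but all comparisons share 1 estimate of the spread per gene. Genes with a low estimate are favoured for a call at every age, so the lists are not independent and these p-values overstate the recurrence. By how much was not tested. Called at all 3 ages were Cdkn2a (1.66, 2.31 and 3.87), Cd44 (0.92, 1.10 and 0.57), Cd83 (0.94, 0.83 and 0.47), Tunar (0.95, 0.89 and 0.70), Tubb6 (0.50, 0.49 and 0.28) and Ezh1. Log2 fold changes correlated across genes, which are not independent replicates, with r = 0.218 between 6 weeks and 3 months, 0.334 between 6 weeks and 6 months and 0.378 between 3 and 6 months. Averaged over the 3 ages, 1021 genes were higher and 837 lower in dKO.

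In WT alone, 1676 genes were higher and 2136 lower at 6 months than at 6 weeks (n = 4 and 3). Shox2, a homeobox gene, rose by 3.50 ± 0.58 (adjusted p = 0.000513), Pmch, the melanin-concentrating hormone precursor, by 3.14 and Slc17a6 by 2.82 ± 0.39. Spp1 rose by 2.53 ± 0.31, Abca8a by 2.45 and Gfap by 1.65 ± 0.22. Aplnr, the apelin receptor, fell by 2.91 (adjusted p = 1.47e-09), Tia1 by 3.08, Dkk2, a Wnt antagonist, by 1.92, Zfp932 by 1.89 and Rras2 by 1.83. With the mean of probe sets Aplnr and Tia1 fell by 1.64 and 0.78, still called, and the Tia1 call ended with the Gapdh covariate (adjusted p = 0.158). Shox2 rose by 1.29 with the probe set of highest mean, still called, and its call (1.46, adjusted p = 0.134) and those of Slc17a6 and Pmch ended with the 3 tissue covariates. For Slc17a6 this decides nothing on tissue, because it is on the thalamic or pallidal list that gives 1 of these covariates. Cholesterol synthesis genes had 15 of 20 lower and none higher, also adjusted over the list alone, with a median of -0.56 (set adjusted p = 4.79e-12, and adjusted p = 0.0736 with an estimated correlation). Cyp51, Hmgcs1 and Mvd fell by 1.08, 0.99 and 0.97. Activated microglia genes had 11 of 17 higher (13 adjusted over the list alone; set adjusted p = 7.09e-06, and adjusted p = 0.152 with an estimated correlation), and MHC class I and complement genes 6 of 12, among them H2-K1 (0.69) and B2m (0.60), and 9 adjusted over the list alone (set adjusted p = 1.49e-05, and adjusted p = 0.152 with an estimated correlation). Thalamic or pallidal markers had 5 of 10 higher, with Slc17a6 first and Prkcd by 2.23, and 8 adjusted over the list alone (set adjusted p = 2.04e-04, and adjusted p = 0.405 with an estimated correlation). Medium spiny neuron genes had 8 of 40 lower, with Rgs9 down by 1.15, and 2 higher and 9 lower adjusted over the list alone (set adjusted p = 0.00265, and adjusted p = 0.603 with an estimated correlation). The count of 3812 genes was 1885, 1964 and 2345 without WT replicate 1, 2 or 3 of 6 weeks, and 2541 and 2480 without WT replicate 2 or 4 of 6 months. It was 383 with the Gapdh 3' minus 5' difference as a covariate and 631 with 3 tissue marker medians as covariates. That Gapdh difference itself averaged -0.137 in WT at 6 weeks and 0.0202 in WT at 6 months. Xist was high in 0 of 3 WT arrays at 6 weeks and 3 of 4 at 6 months, and fewer genes were called with Xist as a covariate. Age is therefore mixed with sex here. It also cannot be told apart from any difference between array batches, since the labels give no batch.

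None of 18 comparisons of array medians, interquartile ranges and control probe sets between genotypes had an adjusted p under 0.05, but the 20 splits at 6 weeks are too few for any to pass and the 35 at 3 months leave little room, so this says little on RNA quality. The largest difference by p was the interquartile range at 6 months, 0.307 ± 0.0448 in dKO and 0.234 ± 0.0152 in WT (SD, n = 6 and 4, exact permutation p = 0.019, adjusted p = 0.257). Xist, the transcript of the inactive X chromosome, was high in 0 of 3 WT and 1 of 3 dKO arrays at 6 weeks, in 2 of 4 and 2 of 3 at 3 months, and in 3 of 4 and 4 of 6 at 6 months. The 6-week counts go against the matching for sex that the design text states. With Xist as a covariate, 44 genes were higher and 40 lower at 6 weeks.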

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

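Chosen only after the results were seen were the tests of age, of genetic background and of a loss acting alike at 6 weeks and 3 months, those of a WT sample (of any age) or a mixture under a dKO label, those of neighbouring tissue at 6 months and with thalamic or pallidal markers, and the splits with the shared dKO effect removed. The explanation by a loss acting alike was also restated after its value was known.

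Single arrays stood apart from the rest of their group in 27 of 534 groups of values (5.06%), by the gap to the nearest array over the range of the group, and chance gives about 1 in 20. All 27 were in the groups of 4 and 6 arrays. Whether groups of 3 arrays were among the 534 is not shown, so this says nothing on the 6-week arrays or on dKO at 3 months. WT replicate 1 of 6 months had 9 of these, with ratios of 0.884 for Cuedc1, 0.882 for Spp1, 0.887 for Cd72, 0.91 for Kcnab1, 0.915 for S100a10, 0.845 for Kcnj8 and 0.866 for Folr1, and of 0.913 and 0.861 for the Hox and choroid plexus list medians. The dKO replicate 2 of 6 months had 8, with 0.781 for Taf15, 0.706 for Cdkn2b, 0.689 for Ttr and 0.908 for Folr1, and 0.684, 0.713, 0.885 and 0.857 for the direct pathway, indirect pathway, choroid plexus and interneuron list medians. The dKO replicate 4 of 6 months had 0.738 for Aebp2, 0.655 for Chrm4, 0.692 for Egr1 and 0.674 for Tap2. The others were dKO replicate 1 (Slc24a2, 0.77) and WT replicate 2 (Drd1, 0.898) of 6 months, WT replicate 4 of 3 months (Cuedc1, 0.932, Gdpd1, 0.84, and Pmch, 0.873) and WT replicate 1 of 3 months (Aplnr, 0.88).

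The dKO effect differed between 6 weeks and 6 months in 212 genes, between 6 weeks and 3 months in 3, and between 3 and 6 months in 335, by the interaction test. From 6 weeks to 6 months the changes were 5.05 for Hoxd10, 4.94 for Hoxc8, 4.44 for Hoxa9, 4.26 for Hoxc10, -2.20 for Gpx6, -2.14 for Ramp3, -2.10 for Cckar, -1.79 for Igsf1 and -1.79 for Gkn3. From 6 weeks to 3 months they were 1.99 for Irx5, 1.24 for Zfp932 and -2.44 for Cuedc1. From 3 to 6 months they were 4.76 for Hoxd10, 4.63 for Hoxa9, 3.76 for Hoxc10, 3.55 for Tbx20, 3.48 for Hoxc8, -2.69 for Gpx6, -2.21 for Gkn3, -2.11 for Dmkn, -1.94 for Ido1 and -1.83 for Abi3bp. Outside the genes compared, 240 of 6958 probe sets without a single gene symbol differed at 6 months, 110 higher and 130 lower in dKO.

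Other splits of the same arrays were fitted in the same way. At 6 weeks the 10 splits are too few for a share under 0.05: the real split called 43 genes and the highest other 0, so 1 of 10 reached the real count. Chance alone is argued against at 3 months (1 of 35 splits reached 86 genes, highest other 3) and at 6 months (1 of 100 reached 3727, highest other 1203). The same holds for the mean effect (1 of 100 reached 1858, highest other 166). At 3 months 1 of 35 is the smallest share possible, and the sets of 100 are samples of the possible splits. These shares were not adjusted for the number of such tests. For the changes between ages the plain splits decide nothing, because a dKO effect exchanged at 1 age becomes a difference between ages: 3 of 100 reached 212 from 6 weeks to 6 months (highest other 2088), 9 of 100 reached 3 from 6 weeks to 3 months (highest other 143) and 2 of 100 reached 335 from 3 to 6 months (highest other 1849). The structure that the highest of them follow is the genotype. They exchanged WT replicates 1 and 2 of 6 weeks with dKO replicate 2 and the library labelled dKO replicate 3, or put dKO arrays in all 4 WT places of 6 months. After the dKO effect shared by the ages was subtracted, chance alone is argued against from 6 weeks to 6 months (1 of 100 reached 212, highest other 2). It is also argued against from 3 to 6 months (1 of 100 reached 335, highest other 18), but not from 6 weeks to 3 months (9 of 100 reached 3, highest other 44). For WT at 6 months against 6 weeks 2 of 35 reached 3812, and the other of these (3999) exchanged all 3 arrays of 6 weeks with 3 of the 4 of 6 months and so holds the same age difference. These splits do not decide on chance there, and the highest of the 30 that mix the ages called 32.

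In 24 of the 43 genes called at 6 weeks, the 3 WT arrays of that age lay beyond all 20 other arrays, as they did in 508 of all 20694 genes tested, where chance gives 0.113%. Every other group also lay apart in more genes than by chance. The counts were 177 for dKO at 6 weeks and 55 for dKO at 3 months (chance 0.113%). They were 281 and 103 for WT at 3 and 6 months (chance 0.0226%), and 999 for dKO at 6 months (chance 0.00198%). The median difference of the 24 genes, signed by 6 weeks, was 0.95 at 6 weeks, 0.18 at 3 months (ratio 0.185) and 0.70 at 6 months, but a loss of Ezh1 and Ezh2 acting alike at 6 weeks and 3 months cannot be told apart by this ratio, because the genes were chosen for 6-week WT arrays beyond those of 3 months, which lowers it. Age may contribute to the distance from the older arrays: from 6 weeks to 6 months the same genes changed in dKO in the direction of WT by 0.735 of its median change (bootstrap interval 0.523 to 0.948). It does not account for the difference from the dKO arrays of 6 weeks, which have the same age by their labels. Genetic background differing between the 6-week control and dKO mice may contribute too, as 9 of 40 located 6-week calls other than Ezh1 were on its chromosome, 11, with 3.17 by chance (one-sided Fisher's exact test over genes, which are not independent, p = 0.00351). Within that limit on age all stay open, and a genotype effect peculiar to 6 weeks was not tested.

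The library labelled dKO replicate 3 of 6 weeks had higher Ezh1 values than the other dKO arrays and little of the later rises. Over the 66 genes higher at both 3 and 6 months its median was -0.305, inside the -0.53 to -0.16 of the 11 WT arrays, above the -0.52 to -0.47 of the WT arrays of its age and below the 0.21 and 0.01 of dKO replicates 1 and 2. A mixture of WT and dKO tissue cannot be told apart: on the line from WT to dKO replicates 1 and 2 the 4 Ezh1 probe sets had a median position of 0.557 (0.473 to 0.822) and the 66 genes one of 0.259 (bootstrap interval 0.0693 to 0.378), but these 2 dKO arrays differ, each placed by the other at 0.65 to 1.54. The 0.105 of 37 genes with a difference of at least 0.5 decides nothing, because that choice lowers it. A WT sample of 6 weeks is argued against, since all 4 Ezh1 probe sets lay below every WT array of that age, and their median difference from its WT mean was -4.41 SD of WT arrays within ages (-5.84 to -2.50). From WT of 3 months (0) to WT of 6 weeks (1), over genes parting them by at least 0.5, its lowest median position was 0.633 against -0.0571 to 0.260 in left-out WT arrays of 3 months, which argues against a WT sample of that age; from WT of 6 months it was 0.732 against 0.00909 to 0.373, short of the bound set for that test. A later test on cholesterol synthesis genes, added because of that shortfall, argues against both ages, at 6.57 and 8.77 SD of WT arrays within ages from their means (7 and 6 of 27 lists lay over 3 SD away and beyond all WT arrays, and 3 for WT of 6 weeks), if these differences follow age and not array batch. A WT sample of an age not on the arrays cannot be told apart, as 3 of the 4 Ezh1 probe sets lay in the range of all 11 WT arrays and the fourth, at 0.13, below 0.469, and an incomplete loss of Ezh1 in that animal was not tested.

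Medium spiny neuron genes had a lower median in dKO at 6 weeks (-0.52, none called) and at 6 months (-0.75). With an estimated correlation neither set test passed (camera, adjusted p = 0.106 and 0.128). Cortical and choroid plexus markers varied between arrays. With both marker medians as covariates the list's median was -0.388 at 6 weeks and -0.657 at 6 months. That was 0.751 of its size (bootstrap interval over genes 0.651 to 0.846) and 0.876 of its size (0.763 to 0.950), with 1 and 31 genes called lower. With the thalamic or pallidal median added it was -0.459 (0.888 of its size, 0.589 to 0.979) and -0.657 (0.876, 0.760 to 0.946). The counts were 0 and 31, against 0 and 30 without covariates. The genes are not independent and marker medians may correct too little, so these intervals alone do not decide on neighbouring tissue. At 6 months such tissue as the whole cause is argued against. The list's medians did not overlap there (-0.69 to -0.42 in dKO, 0.03 to 0.20 in WT), while the cortical, choroid plexus and thalamic or pallidal medians did. At 6 weeks neighbouring tissue stays open. The dKO array with the highest list median, 0.33, lay inside the WT range of 0.24 to 0.51 and had the lowest cortical median, -0.90. The dKO array with the lowest list median, -0.48, had the highest cortical median, 0.99. The list's median log2 fold change was -0.75, -0.30 and -0.52 without dKO replicate 1, dKO replicate 2 and the library labelled dKO replicate 3. Loss of medium spiny neurons and lower expression within them stay open, as bulk tissue values do not separate them.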

How the results depend on the processing

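Of 7581 values of named genes under settings other than leaving out an array, 7196 stayed on their side of the threshold (148 of them, called in neither fit, changed sign), 243 lost the call, 132 gained one and 10 reversed; leaving out each array left 10653 of 10971 on their side (139 with a changed sign), 255 lost, 63 gained and 0 reversed. Of 324 list tests 256 stayed on their side (7 with a median of changed sign), 57 lost and 11 gained, and leaving out arrays left 1781 of 1863 there (30 with a median of changed sign), lost 46, gained 35 and reversed 1. The probe set of highest mean, the SD filter, the high-Xist subset, the 2 sets of tissue covariates and leaving out 150 genes on either side of Ezh1 were chosen after seeing the data, and the last moved no count over 1.5 times. At 6 weeks only 3 of those 300 genes were called, so the count could fall only from 43 to 39. Other calls on the chromosome of Ezh1 stayed in, so this setting decides nothing on genetic background. The dim-probe filter was not run, and the source table moved nothing, as its values are identical. The cause was not tested unless the setting itself tests fewer genes or arrays or is stricter. Array number limits all counts, and signal over background is unknown after centring.

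Quantile normalization gave 178 higher and 23 lower at 3 months and 11 for the change from 6 weeks to 3 months (main value 3). That last count was 5 with centring, with the mean of probe sets (3 lower at 3 months), without shared-probe sets and with the highest mean, and 6 with the SD filter. Own 2-group fits gave 4 and 3 at 6 weeks, 139 and 21 at 3 months, and 953 and 906 at 6 months, and give no interaction or mean effect. Trend with robust gave 16 higher at 6 weeks and 1 from 6 weeks to 3 months. Every probe set gave 30 lower at 6 weeks. Array weights, which put 4.79 on the library labelled dKO replicate 3 of 6 weeks, gave 1231 and 1360, 247 and 76, then 2149 (6 weeks to 6 months), 638 (6 weeks to 3 months), 1154 (3 to 6 months), 8414 (WT age) and 3657 (mean effect). In the same order, adjusted p under 0.01 gave 2 and 1, 50 and 2, and 942 and 960 at 6 months, then 95, 98 (3 to 6 months), 1451 and 866, and a log2 fold change of at least 1 gave 8 and 6, 47 and 1, 202 and 121, then 116, 158, 274 and 76, with 12 medium spiny neuron genes lower. Xist as a covariate gave 44 and 40 at 6 weeks, 433, 8 and 2133 (WT age). The Gapdh covariate gave 12 and 11 at 6 weeks, 3 lower at 3 months, 5 from 6 weeks to 3 months, 383 (WT age) and 1001 (mean effect). High-Xist arrays of 6 months gave 41 and 46 at 6 weeks, 26 lower at 3 months, 838, 1133 and 6142 (WT age). Tissue covariates gave 57 and 37 at 6 weeks, 16 lower at 3 months, 579 and 526, and with the thalamic or pallidal median added 17 lower at 3 months, 71 (6 weeks to 6 months) and 631 (WT age).

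The replicate block, on 20 arrays, gave 2 and 2 at 6 weeks, 35 and 1 at 3 months, 1223 higher at 6 months, 118, 0 (6 weeks to 3 months), 82 and 953 (mean effect), and no WT age value. Numbers did not pair the arrays: the correlation of deviations over 10 pairs ran from -0.388 to 0.174, and 1 array correlated best with its own number.

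With the highest-mean probe set, Clvs1 (0.0611), Gdpd1 (0.0556) and Patj (-0.0583) reversed at 6 weeks, Eya1 (-0.0149) at 3 months, and Aebp2 (0.0357), Gdpd1 (0.24), Lss (-0.20), Neurod2 (-0.12), Ptprc (0.0029) and Tap1 (-0.0568) at 6 months. The oligodendrocyte set test of 6 weeks read -0.00027 without dKO replicate 1 and 0.373 without dKO replicate 2 (main value 0.168).

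Leaving out each array gave 2 to 121 higher and 1 to 152 lower at 6 weeks, 39 to 98 and 2 to 13 at 3 months, 1316 to 2221 and 1409 to 2223 at 6 months, 122 to 470, 3 to 12 and 118 to 680 for the changes to 6 months, to 3 months and from 3 to 6 months, 1885 to 5151 for WT age and 1297 to 2243 for the mean effect. Hox genes higher at 6 months numbered 28 to 31, other developmental factors 54 to 60 and medium spiny neuron genes lower 29 to 31.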

Other observations

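The split of Hox genes by cluster and the list of transmitter and neuropeptide genes of other neuron classes were chosen only after the gene table was seen. At 6 months all 10 measured genes of cluster A rose (median 1.30), 7 of 9 of cluster B (1.27), 7 of 7 of cluster C (1.72) and 7 of 9 of cluster D (1.58). At 3 months 3 of 7 genes of cluster C rose, 1 of 9 of B, 1 of 9 of D and 0 of 10 of A. Hoxa9 read 0.07 ± 0.16 at 3 months and rose by 4.70 ± 0.13 at 6 months, while Hoxc8 rose by 2.09 ± 0.22 and 5.57 ± 0.18, and Irx5 by 2.63 ± 0.21 and 2.94 ± 0.18. Whether clusters differ from each other was not tested.

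Genes of transmitters and neuropeptides used by other neuron classes did not rise as a set at 6 months. Of 38 measured, 2 rose, Slc6a5 (4.11) and Adcyap1 (1.37), and 3 fell, Pmch (-3.32), Slc18a2 (-1.14) and Tph2 (-0.44), with a set p of 0.95 and 0.97 with an estimated correlation. Pmch had risen by 3.14 in WT from 6 weeks to 6 months. Spp1 and Gfap, higher in dKO at 6 weeks by 1.73 and 1.21, read 0.73 and 0.04 at 6 months without passing the test, and rose with age in WT by 2.53 and 1.65.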
